A study of Mus musculus with 3 samples.

How the data were processed

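Ribosome-depleted total RNA from the chromatin fraction of mouse macrophages was sequenced in 3 libraries of 1 group. Per the file headers and the archive's text listing of each library, the authors quantified reads against annotation M21 of assembly mm10 and did not pool replicates. Expected counts per gene and per transcript were deposited by the authors in a column layout like that of RSEM. A second set of transcript tables, in a layout like that of kallisto, holds the estimated counts that the authors made from the reads without an alignment file among the inputs, and is called the kallisto tables here. The names and versions of both tools, the aligner and the use of strand are not given in the sources used here. TPM values, deposited by the authors, are scaled over all entries of a file, so a large share of small RNAs lowers the TPM of every other gene. The authors also deposited a signal column pair, the lower and upper bounds of a credibility interval in TPM, whose level is not given in the sources used here.

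Effects of this processing on the values are as follows. Gene tables count reads over annotated exons, so unspliced RNA is represented through retained-intron and other isoforms. Very short genes have effective lengths of a few bases, which inflates their TPM. Without a statement on strand, a gene and an overlapping antisense gene cannot be told apart, and genes with near-identical copies are uncertain.

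All 55536 gene identifiers of the tables were matched to GENCODE M21 on GRCm38, the build that mm10 names, from which symbols, gene types, transcript types and 1-based coordinates were taken. Entries for 96 ERCC spike-in sequences, for phiX, a sequencing control, and for 26248 numeric identifiers were kept out of the tests. phiX held 1.08%, 0.299% and 0.332% of the expected counts in replicates 1, 2 and 3. Totals were 16317439, 16245280 and 12439931 expected counts, and 25308591, 27754284 and 21107490 estimated counts in the kallisto tables. A count of 0 allows up to 3 counts.

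Gene lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule named up to 5 members with the highest mean TPM and the lowest measured member of each of 24 lists, the 15 protein-coding and 10 other genes with the highest mean TPM, the 5 most variable genes with a mean count of at least 100, up to 10 trend genes each way, and any member of the NF-kB and IkB family and of the Toll-like receptors. A symbol pattern for histones also matched H13, which is not a histone and was left out. List levels are medians of log2(mean TPM + 0.1), set against 10000 random lists of coding genes. The 17 pairs of lists were compared with two-sided permutation tests of 100000 resamples, leaving out genes in both lists, with Benjamini-Hochberg adjustment. Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr, a slope on log2 starting RNA in ng and adjusted p below 0.05. Coefficients of variation are edgeR's tagwise values, compared with 10000 random lists matched on mean log2 CPM in 20 bins, in a two-sided test. Noncoding isoform shares were matched on mean TPM in the same way. Fisher's exact test of the trend lists and the random-list test of deviations per library were added after the data were examined, as was rescaling deviations over coding genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and DESeq2 1.42.0 were also used.

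The tests were tested on simulated data. In counts drawn with the real common coefficient of variation, the trend test made 0 calls without slopes. With 200 changed genes it recovered 74% of slopes of 1 per doubling and 97% of slopes of 2, with 3 other calls. Every simulated gene had the same coefficient, genes were drawn independently, and slopes were placed only in genes with higher counts. Real coefficients lay at 0.168 to 0.304 (percentiles 5 to 95), so these rates need not hold for the real genes. The pair test called 4 of 100 runs without a shift and 52 of 100 with a shift of 3. The variability test called 4 of 100 runs without a change and 99 of 100 with a factor of 1.5. Alternatives covered pseudocounts of 1 and 0.01, posterior mean TPM, kallisto tables, TPM rescaled over coding genes, other detection limits, DESeq2 and its size factors, no filter, other bins, and each replicate left out. With 2 libraries the trend has no residual degrees of freedom, so slopes there are given without a test. Groups of 3 are too small for an outlier test, and no untreated sample was analysed here.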

Results

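The series measured RNA bound to chromatin in mouse bone-marrow-derived macrophages, primary cells of strain C57BL/6J, after 20 min with 100 ng/ml lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4. Chromatin-fraction RNA is enriched for transcripts still being made or not yet released from their genes. There is 1 group of 3 libraries, which the labels call biological replicates 1, 2 and 3, and no untreated group, so levels are reported and no induction. Gene tables held 16317439, 16245280 and 12439931 expected counts in replicates 1, 2 and 3. A count of 0 allows up to 3 counts, or 0.184, 0.185 and 0.241 CPM (counts scaled to the library total). Intervals and floors cover counting error only. The labels give the 3 samples separate biosamples and 1 donor entry, and do not say whether they came from separate animals. The edgeR and DESeq2 tests fit a line on starting RNA amount with 1 library per amount. Each gene has 1 residual degree of freedom around that line, so its scatter was estimated in part from the other genes. The p-values of both tools are set against that partly pooled scatter. They do not measure a spread between libraries of the same amount. All other p-values come from shuffling, randomly drawing or counting genes, which are not independent replicates, and measure the spread over genes.

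The first question was which groups of lipid A response genes were present on chromatin at 20 min. Immediate early genes, the transcription factors and feedback regulators that respond without new protein synthesis, had a median of 71.1 ± 32.0 TPM, a level scaled for gene length and library total (SD, n = 3). NF-kB early response genes, a list of cytokines, chemokines and feedback inhibitors, had a median of 47.8 ± 15.02 TPM (SD, n = 3). Late response genes, most of which are known to need hours of stimulation, had a median of 0.287 ± 0.105 TPM (SD, n = 3). At least 1 TPM in every library was reached by 25 of the 26 immediate early genes, 30 of the 30 NF-kB early genes and 5 of the 24 late genes. In the second set of transcript tables, which gave higher TPM for many genes, 25, 30 and 13 did, and the late list's median log2 level was 0.92, against -1.21. For NF-kB early genes that level was 6.65 there, against 5.58, and for immediate early genes 6.27, against 6.28. Against random lists of coding genes of the same size, the medians of both early lists lay at percentile 100 and that of the late list at percentile 44.4. Percentile 100 was also reached by housekeeping, macrophage marker, TLR4 pathway, interferon-stimulated and ribosomal protein genes. The random lists drew from all coding genes, detected or not, so this percentile does not set the early lists apart.

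Among the immediate early genes, Fos, a subunit of the AP-1 transcription factor (GRCm38 chromosome 12, 85473890 to 85477273, plus strand), was the highest at 282 ± 165 TPM (SD, n = 3). Dusp1, a phosphatase that inactivates MAP kinases, had 218 ± 112 TPM, and the survival factor Mcl1 had 207 ± 86.4 TPM (SD, n = 3 for each). The nuclear receptor Nr4a1 reached 205 ± 59.8 TPM and the kinase Plk2 170 ± 48.7 TPM (SD, n = 3 for each). Fosl1 was the lowest member, at 0.0267 ± 0.0306 TPM (SD, n = 3). Among the NF-kB early genes, Tnfaip2 was the highest at 767 ± 231 TPM (SD, n = 3). Sod2, the mitochondrial superoxide dismutase, had 242 ± 106 TPM, and Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, had 241 ± 72.7 TPM (SD, n = 3 for each). The ubiquitin-editing enzyme Tnfaip3 had 213 ± 77.3 TPM and the chemokine Cxcl2 192 ± 68.8 TPM (SD, n = 3 for each). The glucose transporter Slc2a1 was the lowest, at 1.57 ± 0.225 TPM (SD, n = 3).

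The late list was led by Il18bp, at 20.8 ± 8.61 TPM, and the cytokine Il10, at 19.6 ± 13.7 TPM (SD, n = 3 for each). Cd40 had 5.03 ± 4.38 TPM, Acod1, which makes itaconate, had 4.44 ± 3.18 TPM, and Ebi3 had 3.25 ± 1.81 TPM (SD, n = 3 for each). The second set of transcript tables gave Cd40 a mean of 52.8 TPM and Il10 one of 43.2 TPM. Edn1 was the lowest member with any counts, at 0.00667 ± 0.0115 TPM (SD, n = 3), and Il12a was listed at 0 counts in every library. Interferon-stimulated genes had a median of 14.2 ± 5.24 TPM (SD, n = 3), with 23 of 26 at or above 1 TPM in every library. Stat2 had 99.1 ± 19.9 TPM, Ifi204 96.3 ± 34.3 TPM and Oasl2 90.0 ± 38.4 TPM (SD, n = 3 for each). Oas2 had 87.3 ± 28.5 TPM (SD, n = 3). Cxcl11 was the lowest measured member, at 0.0267 ± 0.0462 TPM (SD, n = 3), and Cxcl9 and Ifnb1 were listed at 0 counts in every library.

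Immediate early genes lay 7.49 above late genes on the log2 scale, and NF-kB early genes 6.79 above them. In both cases the direction was the same in 3 of 3 libraries, and the two-sided permutation test of genes between lists gave an adjusted p of 1.9e-05, from the smallest p that 100000 resamples can give (1e-05). NF-kB early genes also lay 1.74 above interferon-stimulated genes (permutation test, adjusted p = 0.0101, higher in 3 of 3 libraries), a per-library difference of 1.77 ± 0.14 (SD, n = 3). Immediate early and NF-kB early genes were not told apart: the difference of 0.70 had an adjusted p of 0.49 in the permutation test, and was -0.38 in the second set of transcript tables and -0.45 with means in place of medians. NF-kB early genes and macrophage markers were not told apart either (0.14, permutation test, adjusted p = 0.845), with NF-kB early genes higher in 2 of 3 libraries. That difference was -0.06 without replicate 1 and -0.03 without replicate 3. Nor did immediate early genes pass the permutation test against housekeeping genes, with a difference of 1.48 and an adjusted p of 0.188. This difference was 0.48 in the second set of transcript tables and 0.31 with means in place of medians. For immediate early and NF-kB early genes in turn, the differences from late genes were 5.35 and 5.73 in the second set of transcript tables, and among members at or above 1 TPM in a library 4.34 and 3.62 (permutation test, adjusted p = 0.00709 and 0.00287). Differences are on the log2(TPM + 0.1) scale, which understates those of low genes. Genes rather than libraries were shuffled, since an exact sign-flip test over 3 libraries cannot go below p = 0.25.

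**Figure D1:**
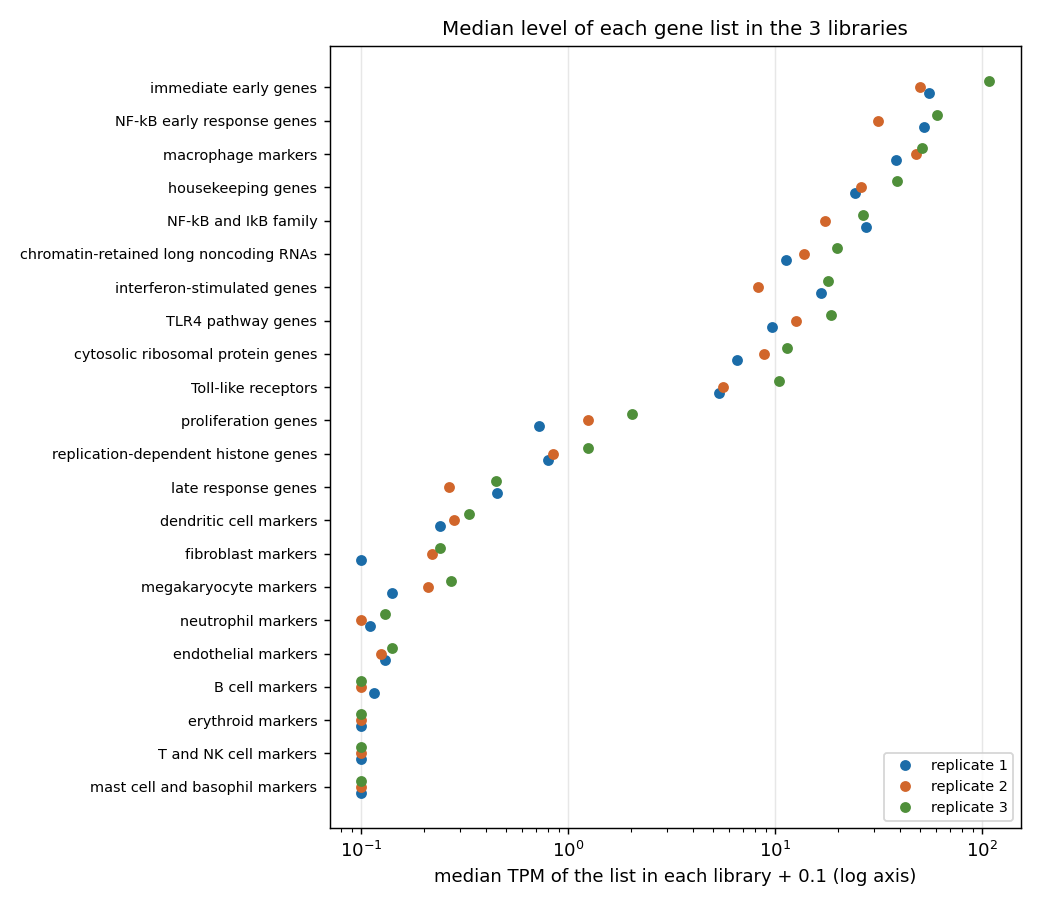
Median TPM of each fixed gene list, plus 0.1, on a log axis, with 1 point per library and replicates offset vertically. The late response list sits near 0.287 TPM, against 71.1 for immediate early genes and 47.8 for NF-kB early genes.

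The machinery that receives the stimulus was measured next. Genes of the TLR4 pathway had a median of 13.5 ± 4.58 TPM (SD, n = 3), and 27 of 28 reached 1 TPM in every library. They lay 5.03 above late genes on the log2 scale (permutation test, adjusted p = 1.9e-05, higher in 3 of 3 libraries), and 1.86 above those among members at or above 1 TPM in a library (permutation test, adjusted p = 0.0483). The co-receptor Cd14 had 191 ± 144 TPM, the kinase Tbk1 82.1 ± 14.8 TPM and Chuk, an IkB kinase, 62.3 ± 12.4 TPM (SD, n = 3 for each). The transcription factor Irf3 had 57.2 ± 11.0 TPM and the IkB kinase Ikbkb 56.1 ± 17.1 TPM (SD, n = 3 for each). The adaptor Tirap was the lowest, at 1.30 ± 0.833 TPM (SD, n = 3). Toll-like receptors had a median of 7.03 ± 2.86 TPM, with 9 of 12 at or above 1 TPM in every library (SD, n = 3). Tlr2 had 29.6 ± 17.9 TPM, Tlr8 27.0 ± 11.3 TPM, Tlr13 21.3 ± 6.60 TPM and Tlr4 itself 11.6 ± 5.24 TPM (SD, n = 3 for each). Tlr11 had 0.0433 ± 0.0252 TPM (SD, n = 3), and Tlr12 was listed at 0 counts in every library.

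All 11 members of the NF-kB and IkB family reached 1 TPM in every library, with a median of 23.7 ± 5.54 TPM (SD, n = 3). In the second set of transcript tables the family's median log2 level was 5.99, against 4.49. Nfkbia, Nfkbiz, Nfkbid, Nfkbie, Bcl3 and Rel are also in the NF-kB early list, so results of these lists are not independent. The IkB members Nfkbia, Nfkbiz and Nfkbid were the highest, Nfkbiz at 115 ± 64.9 TPM and Nfkbid at 56.7 ± 15.4 TPM (SD, n = 3 for each). The precursors Nfkb1 and Nfkb2 had 44.4 ± 11.5 and 26.3 ± 3.39 TPM, and the subunits Relb, Rela and Rel had 16.9 ± 1.90, 15.9 ± 1.48 and 14.4 ± 6.01 TPM (SD, n = 3 for each). Bcl3 had 22.4 ± 4.67 TPM, Nfkbie 21.8 ± 10.9 TPM and Nfkbib 9.42 ± 2.74 TPM (SD, n = 3 for each).

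The purity of the cultures was described with marker lists. Macrophage markers had a median of 45.8 ± 6.69 TPM (SD, n = 3), and 30 of 30 reached 1 TPM in every library. The membrane glycoprotein Gpnmb had 973 ± 323 TPM, the cathepsins Ctsb and Ctsd 441 ± 84.9 and 232 ± 54.7 TPM, and lysozyme Lyz2 171 ± 60.9 TPM (SD, n = 3 for each). Lgals3 had 166 ± 38.7 TPM (SD, n = 3), against a mean of 1669 TPM in the second set of transcript tables. The transcription factor Cebpa was the lowest marker, at 1.60 ± 0.541 TPM (SD, n = 3). Median TPM of the markers of 9 other cell types was at most 0.183 ± 0.0451, in dendritic cell markers (SD, n = 3), and 0 in T and NK cell, erythroid and mast cell markers. These lists lay between 7.24 and 8.76 lower on the log2 scale, in 3 of 3 libraries each. Adjusted p-values of these 9 permutation tests, adjusted with the other pairs over all 17 tested, lay between 1.9e-05 and 1.4e-04. These differences rest on members near 0. In the second set of transcript tables they lay between 6.25 and 9.22, and the highest median log2 levels were -0.14 for megakaryocyte and -0.30 for dendritic cell markers. Among members at or above 1 TPM in a library, macrophage markers lay 2.96 above neutrophil markers (permutation test, adjusted p = 0.0952) and 2.06 above endothelial markers (permutation test, adjusted p = 0.211), and neither difference passed. Because 13 of 15 neutrophil and 6 of 8 endothelial markers lay below 1 TPM in every library, very few genes remained for these tests. Not passing therefore does not show like levels.

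A few markers of other cell types lay well above the rest of their lists. At least 1 TPM in every library was reached by 3 of 15 T and NK cell, 0 of 12 B cell, 1 of 15 neutrophil, 1 of 12 erythroid and 3 of 7 megakaryocyte markers, and by 1 of 9 dendritic cell, 0 of 8 mast cell and basophil, 0 of 10 fibroblast and 2 of 8 endothelial markers. In the second set of transcript tables these counts were 6, 1, 2, 1 and 3, and 3, 0, 1 and 4. The von Willebrand factor gene Vwf had 45.5 ± 7.15 TPM, the neutrophil growth factor receptor Csf3r 39.0 ± 8.58 TPM and the interleukin 7 receptor Il7r 36.1 ± 10.6 TPM (SD, n = 3 for each). Cd4 had 6.17 ± 1.86 TPM and the heme synthesis gene Alas2 5.81 ± 2.03 TPM (SD, n = 3 for each). Ighm, at 0.763 ± 0.567 TPM, was the highest B cell marker, and Mmp2, at 0.557 ± 0.124 TPM, the highest fibroblast marker (SD, n = 3 for each). Kit, at 0.443 ± 0.260 TPM, was the highest mast cell marker, Gp1ba, at 2.67 ± 0.785 TPM, the highest megakaryocyte marker, and Batf3, at 1.86 ± 0.290 TPM, the highest dendritic cell marker (SD, n = 3 for each). Proliferation genes had a median of 1.23 ± 0.660 TPM (SD, n = 3), led by Mki67 at 8.41 ± 1.61 TPM (SD, n = 3).

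Cytosolic ribosomal protein genes, whose mature mRNAs are abundant in whole cells, had a median of 8.80 ± 2.42 TPM (SD, n = 3). The difference from macrophage markers was -2.29 on the log2 scale (permutation test, adjusted p = 1.9e-05, lower in 3 of 3 libraries). Rpl10 was their highest member, at 117 ± 29.3 TPM (SD, n = 3). Housekeeping genes had a median of 29.6 ± 7.79 TPM, with Eef1a1 at 310 ± 58.5 TPM and Actb at 263 ± 140 TPM (SD, n = 3 for each). Replication-dependent histone genes had a median of 0.863 ± 0.249 TPM, led by Hist2h2ac at 12.5 ± 4.15 TPM (SD, n = 3 for each).

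In all, 11553 of 55536 annotated genes reached 1 TPM in every library, among them 8942 of 22028 protein-coding genes and 227 of 5854 lincRNA genes. The highest protein-coding genes after Gpnmb were the receptor genes Lilrb4a and Lilr4b, at 945 ± 371 and 780 ± 236 TPM (SD, n = 3 for each), neighbours of similar sequence whose reads could be split between them. Hnrnpa2b1, Psap and Sat1 followed at 707 ± 157, 673 ± 86.0 and 626 ± 139 TPM (SD, n = 3 for each). Across 14664 genes, Pearson's r of log2(TPM + 0.1) was 0.901 for replicates 1 and 2, 0.880 for replicates 1 and 3 and 0.885 for replicates 2 and 3, and Spearman's rho lay between 0.928 and 0.930. Over 10377 coding genes, r lay between 0.957 and 0.968. Genes are not independent replicates. The common biological coefficient of variation was 21.3%.

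Composition depended on the unit. Protein-coding genes held 62.8% ± 4.68 of expected counts and 19.5% ± 4.63 of TPM, and snoRNA genes held 0.526% ± 0.326 of counts and 47.5% ± 7.69 of TPM (SD, n = 3 for each). The highest were Gm26447, at 94287 ± 17293 TPM, and Snord22, at 84141 ± 20246 TPM (SD, n = 3 for each). The second set of transcript tables gave snoRNA genes 10.7% of TPM and protein-coding genes 32.5%. Malat1, a long noncoding RNA retained in the nucleus, held 8.55% ± 2.21 of counts, and Neat1 and Xist had 1891 ± 445 and 989 ± 271 TPM (SD, n = 3 for each). The list of chromatin-retained long noncoding RNAs had a median of 14.9 ± 4.46 TPM, and that of small structural RNAs 6300 ± 2359 TPM (SD, n = 3 for each). Rmrp had 2 overlapping gene rows on chromosome 4, so its 55586 ± 21387 TPM in the ribozyme row (SD, n = 3) is uncertain. Rn7s1 and Rn7s2 shared equal values of 13550 ± 1278 TPM (SD, n = 3), as near-identical copies do. Mitochondrially encoded genes held 0.0697% ± 0.0423 of counts (SD, n = 3), led by mt-Co1 at 204 ± 111 TPM (SD, n = 3). Gm26917, Gm42418 and CT010467.1, neighbouring genes within 5815 bp of chromosome 17, held 15.3% of counts in replicate 1 (Wilson 95% interval 15.2 to 15.3), 26.04% in replicate 2 (26.02 to 26.06) and 10.8% in replicate 3 (10.8 to 10.8).

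**Figure D2:**
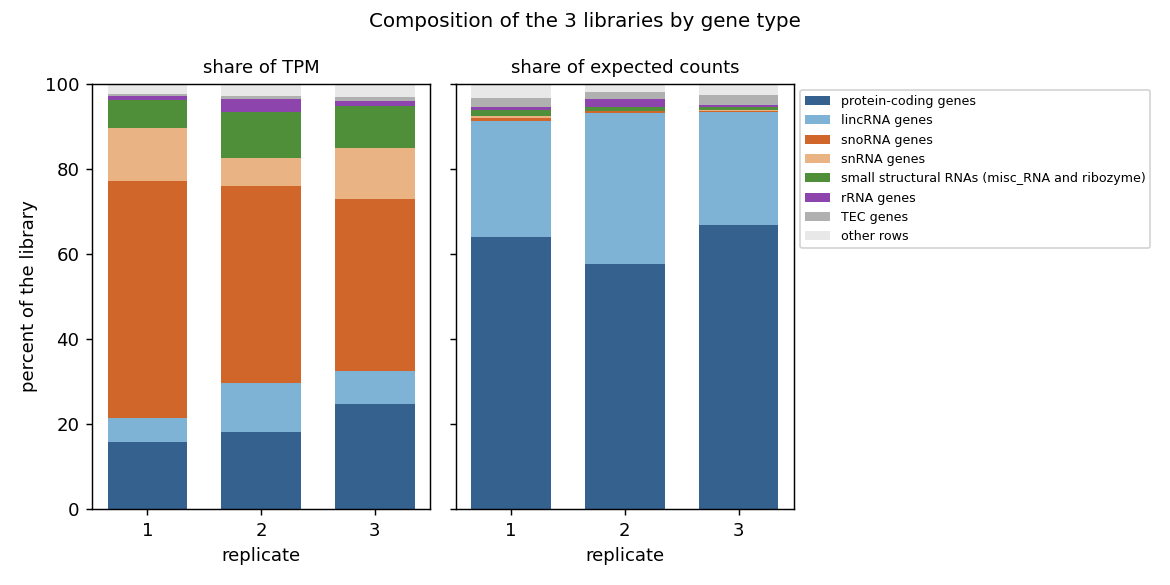
Share of each library, in percent, held by gene types, by TPM on the left and by expected counts on the right, with 1 bar per replicate. snoRNA genes hold a mean of 47.5% of TPM and 0.526% of counts.

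Isoform tables allowed a value for transcripts annotated as noncoding (retained intron or processed transcript). Over 7450 coding genes with such an isoform and at least 1 TPM in every library, they held a median of 48.1% ± 1.57 of a gene's TPM (SD, n = 3). For NF-kB early genes the median was 70.8%, against 54.5% in random lists matched on level (adjusted p = 0.0102 over the 9 lists tested), and values of 68.6 to 74.3% in the 3 libraries. The second set of transcript tables gave 63.9%, against 58.8% in matched lists, which did not pass (random lists matched on level, unadjusted p = 0.42). Immediate early genes, at 47.8%, did not pass (adjusted p = 0.654). Ribosomal protein genes lay higher, at 65.5% against 48.5% (adjusted p = 0.0018), and macrophage markers lower, at 34.9% against 54.4% (adjusted p = 0.0234). The 7 Toll-like receptors with such an isoform lay at 4.27% against 47.7% (random lists matched on level, adjusted p = 0.0054). Their medians within replicates 1, 2 and 3 were 7.84, 7.28 and 7.43%. That call was lost in the second set of tables, where they had 45.2% (random lists matched on level, unadjusted p = 0.475). These tables hold no separate intron values, so reads from unspliced RNA could be counted only through the annotated isoforms. How many were left out was not measured.

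Stimulus-responsive genes varied more between the libraries than genes of like level. The median biological coefficient of variation was 0.32 for NF-kB early genes, against 0.19 in matched random lists, and 0.24 for immediate early genes, against 0.19 (adjusted p = 6.0e-04 for each, from the smallest p that 10000 lists can give, 2e-04). Late genes had 0.30 against 0.20, the NF-kB and IkB family 0.25 against 0.18, and mitochondrially encoded genes 0.32 against 0.19 (adjusted p = 6.0e-04 for each). TLR4 pathway genes, at 0.18, and ribosomal protein genes, at 0.20, did not pass (adjusted p = 0.753 and 0.907). In all, 9 of the 15 lists with enough genes passed. The others past the threshold were interferon-stimulated genes (0.21), macrophage markers (0.21), proliferation genes (0.26) and small structural RNAs (0.25). Without replicate 1, 1 list, small structural RNAs, passed (adjusted p = 0.006), and NF-kB early genes, immediate early genes and late genes had adjusted p = 0.797, 0.797 and 0.645. The coefficients of all genes then lay close together (percentiles 5 to 95 at 0.201 to 0.244, against 0.168 to 0.304 in 3 libraries), so the loss does not show which library carried the spread. With the SD of log2 TPM in place of the coefficient, 5 lists passed: NF-kB early, immediate early, late and proliferation genes and small structural RNAs.

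Relative to all coding genes, the 4 response lists each lay higher in replicate 1 and lower in replicate 2. NF-kB early genes lay 1.07 higher on the log2 scale in replicate 1 than in the mean of the others, and their deviation in replicate 2 was -0.96. The 8 late genes with enough TPM, of 24, deviated by 1.22 in replicate 1 and -1.23 in replicate 2 (0.70 in replicate 1 in the second set of transcript tables, and -0.76 in replicate 2 with a pseudocount of 1), interferon-stimulated genes by 0.58 and -0.56, and immediate early genes by 0.39 and -0.41. Against random lists matched on level, a test added after the data were examined, adjusted p lay between 6.5e-04 and 0.0012 for these values (36 tests). With 1 library on one side, and members of a list that are not independent, these p-values describe the genes of these libraries only. Late genes also passed in replicate 3, at -0.47 (adjusted p = 0.00288). Macrophage markers deviated by 0.09 and 0.04, which did not pass (adjusted p = 0.455 and 0.705). Ribosomal protein genes went the other way, by -0.16 in replicate 1 and 0.22 in replicate 2 (adjusted p = 6.5e-04 for each). Mitochondrially encoded genes deviated by 0.98, 0.13 and -0.94 in replicates 1, 2 and 3, which was not tested. They held 0.118% of counts in replicate 1 (Wilson 95% interval 0.117 to 0.120), 0.0491% in replicate 2 (0.0481 to 0.0502) and 0.0416% in replicate 3 (0.0405 to 0.0428). Proliferation genes deviated by -0.64 in replicate 1 (adjusted p = 0.00257), and by -0.20 with a pseudocount of 1. The NF-kB and IkB family, which shares members with NF-kB early genes, deviated by 0.71 and -0.54 in replicates 1 and 2 (matched random lists, adjusted p = 6.5e-04 for each). Toll-like receptors deviated by 0.31, -0.45 and 0.30 in the 3 libraries (matched random lists, adjusted p from 0.0103 to 0.0349). Immediate early genes in replicate 3, at 0.05 (-0.0090 in the second set of transcript tables), and histone genes in replicate 2, at 0.28, also passed (adjusted p = 0.0199 and 0.00166). TPM of all coding genes itself shifted by -0.51, -0.17 and 0.66 in replicates 1, 2 and 3, and deviations are given relative to these shifts. Fos and Fosb had their lowest TPM in replicate 1. Fos had 113 TPM in replicate 1, 293 in replicate 2 and 442 in replicate 3, and Fosb, chosen after its values were seen, had 22.3, 73.1 and 142 TPM.

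**Figure D3:**
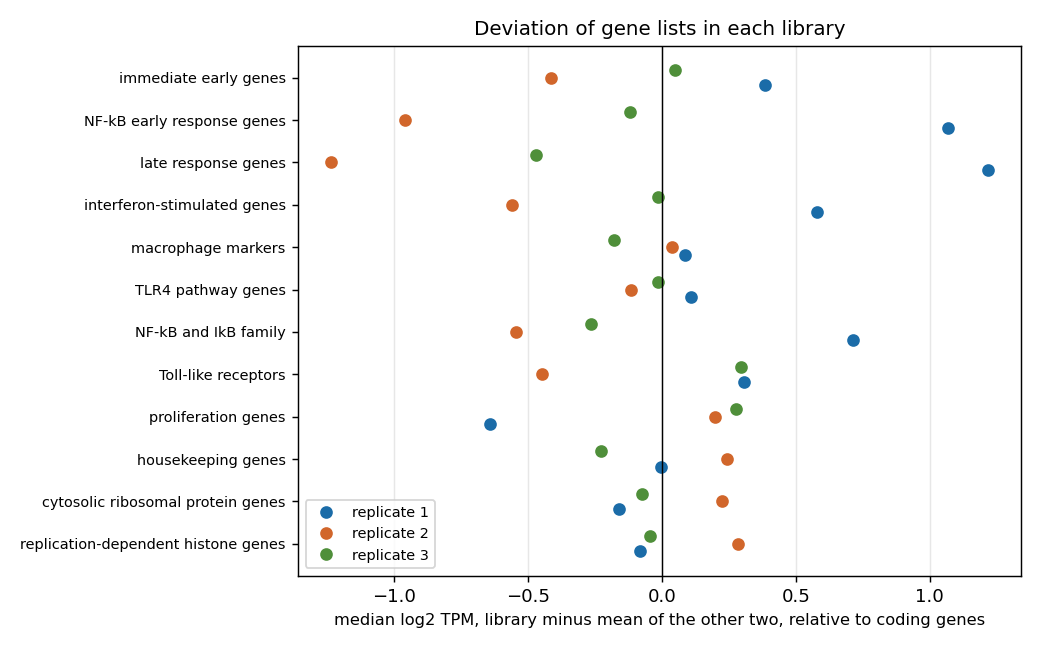
Median deviation of each list in 1 library from the mean of the others, in log2 TPM relative to coding genes (x axis), with 1 point per replicate. NF-kB early genes lie at 1.07 in replicate 1 and at -0.96 in replicate 2, while macrophage markers lie at 0.09 and 0.04.

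The labels give a different starting RNA amount for each library, 1 µg for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3. In edgeR's quasi-likelihood test, 160 of 13985 genes had a slope on the log2 amount at an adjusted p below 0.05, of which 144 were higher and 16 lower with more RNA. NF-kB early genes supplied 14 of the 144 and none of the 16. Of their 30 tested members, 22 were higher and 0 lower when adjusted over the list alone. Late genes supplied 3 of 8 tested members, immediate early genes 4 of 25 and interferon-stimulated genes 4 of 23. DESeq2 called 14 NF-kB early, 2 late, 2 immediate early and 3 interferon-stimulated genes, and the counts tested below are those of edgeR. Fisher's exact test (two-sided) against all other tested genes, over 23 lists, gave adjusted p = 2.3e-19 for NF-kB early genes and between 6.3e-04 and 6.6e-04 for the other 3 lists. The 3 amounts are evenly spaced on the log2 scale, so the slope mainly compares replicate 1 with replicate 2. Fisher's test therefore repeats the contrast of those libraries given above, over genes that are not independent. The NF-kB and IkB family, which shares members with NF-kB early genes, also passed, with 2 of 11 higher (5 adjusted over the list alone, Fisher's exact test, adjusted p = 0.0251). Adjusted over the list alone, 4 late genes, 7 interferon-stimulated genes and 6 immediate early genes were higher, and 1 immediate early gene was lower. Of 30 macrophage markers, 0 passed in edgeR and 0 in DESeq2, with 4 at an unadjusted p below 0.05, and 1 was higher and 1 lower adjusted over the list alone. Of 28 TLR4 pathway genes, 0 passed in either tool, with 0 at an unadjusted p below 0.05. The number of calls depended on the fit: 66 with DESeq2 size factors in edgeR, 84 in DESeq2, 155 with coding genes only, 284 with no filter on low counts and 267 with the second set of counts.

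The steepest slopes belonged to Gm28437, a pseudogene that could share reads with a near-identical copy, at 1.98 ± 0.19 per doubling (SE, edgeR adjusted p = 1.54e-08), and to the T cell co-stimulator Tnfsf9, at 1.93 ± 0.20 (SE, edgeR adjusted p = 8.34e-08). The guanylate-binding protein Gbp5 had 1.86 ± 0.19 (SE, edgeR adjusted p = 5.92e-08). Arl5c, Gm29094, Gem and Icosl, a ligand of the T cell receptor ICOS, had slopes from 1.60 down to 1.51, and Gm24305, Snora70 and Cd40 from 1.47 to 1.43. With a replicate left out, slopes lay between -0.87 and 3.47 for Snora70, 0.58 and 2.16 for Cd40, 0.72 and 2.26 for Gm29094 and 0.85 and 2.01 for Gm24305, each lowest without replicate 1 and highest without replicate 2. Among genes lower with more RNA, Eif4a-ps4 had -1.50 ± 0.27 (SE, edgeR adjusted p = 0.001005) and Lars2, a mitochondrial tRNA synthetase, -1.47 ± 0.20 (SE, edgeR adjusted p = 1.8e-05). Among other genes that were lower, Gm9517 had a slope of -1.33, Col18a1 -0.98 and BC021767 -0.83. Without replicate 2 these slopes were -0.011 for Lars2, -0.41 for Col18a1 and -0.43 for BC021767, and without replicate 1 they were -2.90, -1.50 and -1.23. Against 16 lower calls, edgeR with DESeq2 size factors made 3 and DESeq2 made 2. Other fits made more: 25 with coding genes only, 36 with the second set of counts and 58 with no filter on low counts. DESeq2 did not call Lars2 (adjusted p = 1) at a slope of -1.47, nor Gm9517 (adjusted p = 0.135), and neither fit called Col18a1 or BC021767 (adjusted p from 0.054 to 0.259). Of the named genes that were higher, Snora70 lost its call in both fits (adjusted p = 0.128 and 0.488). The second set of counts did not call Eif4a-ps4, with a slope of -0.38 (edgeR adjusted p = 0.746). With 1 library per amount and 1 residual degree of freedom, the amount cannot be separated from any other property of the libraries. Of the other 2 orderings of the libraries, the one with replicate 2 in the middle called 96 genes and the one with replicate 1 in the middle called 0, with 1255 genes at an unadjusted p below 0.05 in edgeR.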

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

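The tests of NF-kB early genes and of the chromosome 17 genes were chosen after the results were seen, and the test of snoRNA lengths before. The series has 1 group, so no biological difference between groups was tested.

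Reads outside the gene rows lay above the limit that a count of 0 allows. The phiX sequencing control had 176018, 48595 and 41261 expected counts in replicates 1, 2 and 3. Rows with numeric identifiers had 40, 24 and 19. The ERCC sequences had 0 expected counts, and 11, 36 and 43 estimated counts in the kallisto tables.

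NF-kB early genes had lower TPM in replicate 2 than in the other libraries. Scaling by small RNAs is argued against: with TPM rescaled over coding genes the median deviation was still -1.001, with 28 of 30 genes below 0, where the shift of all coding genes was -0.04. Fewer macrophages in replicate 2 would lower macrophage markers there too. Their median deviation in that library was 0.04 relative to coding genes, which argues against it. Macrophage markers lay 0.99 above NF-kB early genes in that library's deviations (permutation test over genes, p = 1e-05, the smallest it can give). NF-kB early genes were flagged for their low values there, so this p-value restates that choice and is no separate support. The starting RNA amount cannot be told apart from other properties of the libraries, since each amount has 1 library; the list's median slope was 0.68 per doubling.

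snoRNA genes held 47.5% of TPM and 0.526% of counts. Their short effective lengths are a candidate explanation: with full gene lengths in place of effective lengths, their share of counts per base was 6.15%. Longer lengths were bound to lower this share, so the check shows the size of the fall and is no separate support. The kallisto tables gave 10.7% of TPM.

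Gm26917, Gm42418 and CT010467.1 took 26.04% of counts in replicate 2. CT010467.1 is annotated as rRNA and overlaps Gm42418 on the opposite strand, so ribosomal RNA left after depletion may be the source. All 3 genes had a higher count share in replicate 2, the smallest ratio to the mean of the other libraries being 1.92, but they were chosen for this pattern. The 353 annotated rRNA genes outside them held 4, 1 and 2 counts, too few to decide, so this source cannot be told apart from others.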

How the results depend on the processing

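Deviations with TPM rescaled over coding genes were chosen after the data were examined. Among the 17 pairs of lists, 161 of 167 alternative values kept their direction and side of the threshold. Of pairs that did not pass, immediate early minus NF-kB early genes turned to -0.38 with kallisto TPM and -0.45 with means of log2 values, and NF-kB early genes minus macrophage markers lay between -0.063 and 0.40 with a replicate left out. The pairs that lost their call used members at or above 1 TPM in a library, where macrophage markers minus neutrophil markers was 2.96 and minus endothelial markers 2.06, at adjusted p = 0.0952 and 0.211. That filter removes low members and leaves fewer genes, which were not separated. Mast cell, B cell and fibroblast markers had too few such members for a value. The mean Pearson r moved from 0.889 to 0.938 with a pseudocount of 1, 0.820 with 0.01, 0.835 with posterior mean TPM, 0.951 with TPM rescaled over coding genes and 0.944 over all genes above 0, and lay between 0.876 and 0.880 with a replicate left out. The common coefficient of variation lay between 0.192 and 0.221 with a replicate left out. The kallisto tables detected 18755 genes. Of 334 list genes at or above 1 TPM, their mean TPM was over 1.5 times higher there for 152 and lower by as much for 12. snoRNA genes held 0.526% of counts and 10.7% of kallisto TPM, miRNA genes 0.0347% of TPM and 23.1% of kallisto TPM, coding genes 62.8% of counts and 32.5% of kallisto TPM, and the chromosome 17 genes 5.95% of TPM. Noncoding isoforms held 54.4% in the kallisto tables and 52.1% in genes at or above 10 TPM.

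Trend calls numbered 66 with DESeq2 size factors in edgeR (63 higher, all 66 shared), 84 with DESeq2 (82 higher, 77 shared), 284 with no filter (226 higher) and 267 with kallisto counts (231 higher, 124 shared). The slope of Smo was 0.056 with kallisto counts. With a replicate left out, the slope of Snora70 lay between -0.87 (without replicate 1) and 3.47, and that of Rpl3-ps1 between -2.76 and 0.54 (without replicate 2). Named trend genes lost their call in 21 of 85 alternatives with a test. Lists past the variability threshold numbered 5 with the SD of log2 TPM and 1 to 8 with a replicate left out, the 1 without replicate 1, where the coefficients of all genes lay close together. The medians of 10 lists changed sides of their matched lists in 19 alternatives, 0 of them past the threshold. With the SD these were macrophage markers (0.349), TLR4 pathway genes (0.426), housekeeping genes (0.369), chromatin-retained long noncoding RNAs (0.416), ribosomal protein genes (0.446) and mitochondrially encoded genes (0.359), and with 10 bins the long noncoding RNAs (0.192). With a replicate left out, medians of the lists that changed sides lay at 0.192 to 0.211 for macrophage markers, 0.169 to 0.206 for TLR4 pathway genes, 0.205 to 0.259 for the NF-kB and IkB family, 0.178 to 0.230 for Toll-like receptors, 0.224 to 0.258 for proliferation genes, 0.1799 to 0.219 for the long noncoding RNAs, 0.195 to 0.220 for ribosomal protein genes and 0.209 to 0.223 for histone genes. The deviation of immediate early genes in replicate 3 was -0.0090 with kallisto. The causes were not tested. Depth limits genes under 3 counts, or 0.241 CPM in replicate 3.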

Other observations

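The tests below were chosen after the results were seen. Variable genes beyond the lists included the lincRNA Gm23925, with 2546, 1399 and 528 TPM in replicates 1, 2 and 3, and the pseudogene Gm9845, with 20.9, 7.31 and 2.49 TPM. Among genes chosen after their values were seen, the transcription factor Irf1 had 618, 220 and 454 TPM, with a slope of 0.96 ± 0.21 per doubling (SE, edgeR adjusted p = 0.00952). Lars2 had 6.55, 36.2 and 11.3 TPM, highest in the library where the chromosome 17 genes were highest. The Y-linked gene Uty had 0 expected counts in every library, and a mean of 6.42 TPM in the kallisto tables, while Xist had 989 ± 271 TPM (SD, n = 3).

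A hypothesis was that the response had gone further in replicate 1 than in replicate 2, so that genes of later groups would have a higher ratio of replicate 1 to replicate 2 than immediate early genes. The stated test, late and interferon-stimulated genes together against immediate early genes, gave a difference of medians of 0.32 on the log2 scale (two-sided permutation test over genes, p = 0.0741, adjusted p = 0.0741), and did not pass. It was 1 of 5 contrasts run. Late genes alone lay 1.35 above immediate early genes (adjusted p = 0.00207, permutation test) and NF-kB early genes 0.99 above them (adjusted p = 3.5e-04, permutation test), while interferon-stimulated genes lay 0.30 above (adjusted p = 0.0741, permutation test). Late and interferon-stimulated genes lay 0.70 above housekeeping genes (adjusted p = 0.0103, permutation test). The hypothesis stays open: the contrast stated for it did not pass, the others were read beside it, and 1 library on each side cannot separate timing from the strength of the stimulus or from the starting amount.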
